A study of Drosophila melanogaster with 3 samples.

How the data were processed

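The samples were mixed-sex whole Drosophila melanogaster embryos collected 0 to 18 hours after laying. They came from a transgenic line in which Nf-YC carries green fluorescent protein at its C terminus. Nf-YC is a histone-fold subunit of NF-Y, the trimer known to bind the sequence CCAAT. Chromatin bound by the tagged protein was recovered with an antibody against the tag and sequenced. The labels give 3 biological replicates, 1 group and no second condition, so no comparison between conditions was possible.

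Per the deposited notes, peaks were called for each replicate from its own alignment and 1 control alignment shared by all, then again on the 3 replicates pooled. The thresholded set came from the replicate and pooled lists by the irreproducible discovery rate (IDR). The genome build of the files is dm6, per the labels. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The strength of each peak is the signal value of the authors' caller, a score with no stated unit. It was used to describe and rank peaks within a list, and for means and correlations across replicate lists. It was not scaled between lists. The deposited lists also give a −log10 q-value per peak. It was saturated, with all 7476 IDR-thresholded peaks at 4.24, and was not used for ranking. Each replicate list and the pooled list held exactly 30000 peaks, so their length was set by a limit and not by the binding. The files hold no read counts. The depth of each library is therefore unknown, and no interval resting on depth is given. The control alignment and the reads were not analysed here.

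Coordinates were read on the Release 6 genome sequence and the Ensembl release 115 annotation of it (BDGP 6.54). All peaks lay on the 6 arms 2L, 2R, 3L, 3R, 4 and X, and 0 extended beyond a chromosome end. A peak was placed by its summit. It was a promoter peak when the summit lay within 500 bp of a transcription start site (TSS) of a protein-coding transcript, and a gene was called bound when a summit lay within 500 bp of any of its TSSs. There were 13945 protein-coding genes on these arms. Coordinates are 1-based.

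Replicates were compared over the 7476 highest-signal peaks of each list, with summits within 100 bp counted as shared and a chance level from 1000 circular shifts per arm. The promoter share was set against 1000 sets of random positions matched by arm. CCAAT on either strand was searched within 100 bp of the summit. Each promoter peak was paired with a window at the same offset from the TSS of a gene with no summit within 1000 bp of any TSS, drawn at random. Centring compared CCAAT density within 50 bp of the summit with that 300 to 500 bp away, with a bootstrap interval over peaks from 1000 draws. All 2080 hexamers, reverse complements merged, were tested in the same windows and called at an adjusted p of 0.05 and an odds ratio of at least 1.5. Gene lists were fixed before the data were examined, as were the tests and most of the other settings tried. Of 42 lists, 41 had at least 5 matched genes and were tested against all other protein-coding genes. All shares were compared with two-sided Fisher's exact tests, and families of tests were adjusted by the Benjamini-Hochberg method. Odds ratio intervals are 95% intervals on the log scale. Where a cell of a list's table was empty, 0.5 was added to each cell for the odds ratio. Peaks and genes are not independent biological replicates, so these p-values describe the peak set and not the spread between embryo collections.

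Genes were named by a rule fixed in advance. It took the gene nearest to each of the 15 strongest peaks, the 5 strongest peaks over 1000 bp from every TSS, and up to 4 members with the strongest peaks for each list past the threshold. It also took every NF-Y subunit and every member of a list of 12 candidate genes. Replicate values are the mean ± SD over the replicate lists with a summit within 100 bp. The median signal was 61.6, 45.3 and 29.0 in the lists of replicates 1, 2 and 3. An SD of signals therefore holds differences in scale between lists as well as any spread between collections. One gene taken by this rule is not reported here. Genes outside the rule are named where stated as chosen after their values were seen, or where a named summit lay in them or nearer to them. A gene counted as bound need not be the nearest one, and 13 of 72 named promoter peaks lay nearer to a TSS of another gene.

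Alternatives covered stricter and pooled peak sets, each replicate left out in turn, other windows, other TSS definitions and other controls. Leaving out a replicate meant keeping peaks among the 7476 strongest of both other lists. That left 4752 to 5532 peaks, so a change there can come from the stricter set as well as from the replicate. The script was tested on simulated data. A hexamer planted in 10% of control windows had the lowest p of 2080, and 0 hexamers were called between random sets of control windows. A planted list bound at 80% against a base of 30% was recovered in 100 of 100 draws, with 0.15% of the other lists called. A promoter was called repeated when under 50% of the 31-mers within 250 bp of the outermost TSS occurred once in the assembly, and unique at 90% or more. Computation used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9.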

Results

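Binding of tagged Nf-YC in whole embryos was described by 3 replicate peak lists, a pooled list and an IDR-thresholded set of 7476 peaks. The set formed 6562 merged regions covering 3.01 Mb, with a median peak width of 471 bp. It was identical to the 7476 highest-signal peaks of the pooled list. Library depth is unknown, and all 3 replicates belong to 1 group. Signals were not scaled between replicate lists, so an SD of signals below also holds differences in scale between the lists.

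The strongest peak lay 140 bp upstream of a TSS of toy, a Pax6 homologue of eye development, on chromosome 4 (988412 to 990211, intergenic). Its signal was 81383, and 27187 ± 4092 (SD, n = 3) in the replicate lists, where it ranked 1 in each. The second lay 267 bp upstream of opa, a zinc-finger pair-rule gene, on 3R (4851788 to 4853357, intergenic), with a replicate signal of 24722 ± 5447 (SD, n = 3). The third was 112 bp upstream of Calr, which encodes the endoplasmic reticulum chaperone calreticulin, on 3R (9629777 to 9631975), with 18856 ± 6858 (SD, n = 3). Peaks close to caup, scro, ap, retn and trh, genes for developmental transcription factors, were also among the 15 strongest. The summits lay 136, 236, 153, 208 and 846 bp upstream of a TSS, and those at ap and trh were in introns of the same genes. The Polycomb group paralogues Su(z)2 and Psc also had peaks among the 15 strongest, 123 bp upstream of the TSS and 156 bp downstream of it in the 5′ UTR. The remaining promoter peaks of the 15 were at L, 313 bp upstream in an intron, and at E(bx), which encodes a subunit of a nucleosome remodelling complex, 58 bp upstream.

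Of the 5 strongest peaks over 1000 bp from any TSS, 3 were among those 15. Their nearest genes were CG15629 on 2L, CG13321 on 2R and CG6465 on 3R, with summits at 4811717, 12956025 and 10665188. The other 2 were nearest to Rh5 on 2L and CG13323 on 2R, at 12010258 and 13042282. All 5 were intergenic. Their mean replicate ranks lay between 11.3 and 29.3, but the spread was wide, with an SD of 35.2 (n = 3) at Rh5. Ranks in replicates 1, 2 and 3 were 8, 10 and 70 at Rh5 and 5, 4 and 29 at CG15629. They were 4, 5 and 33 at CG13321, 12, 14 and 41 at CG13323, and 15, 13 and 6 at CG6465. Replicate 3 thus gave the weakest rank at each except CG6465.

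**Figure D1:**
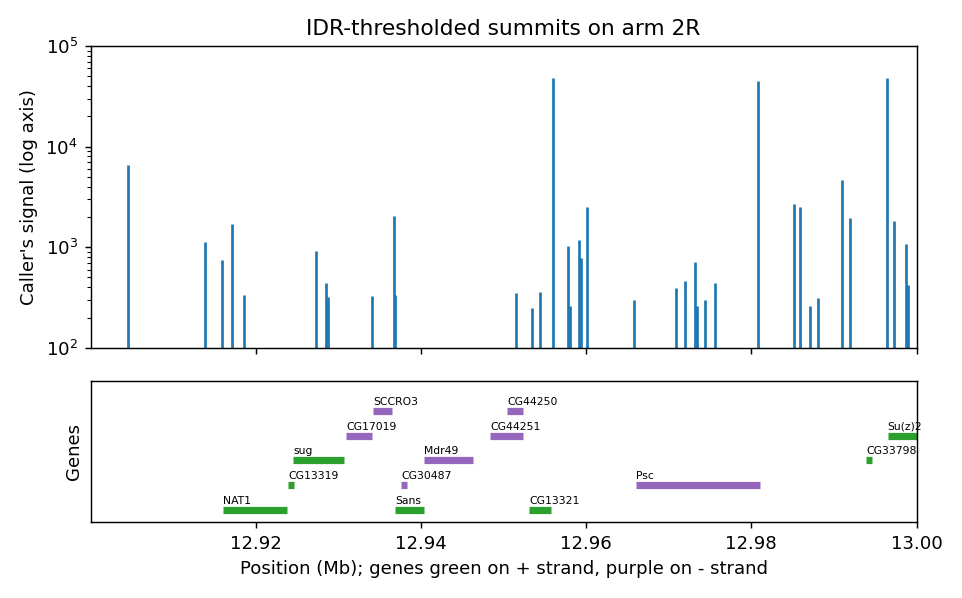
Signal of each IDR-thresholded summit (vertical axis, log scale) against position on arm 2R in Mb (horizontal axis), from 12900001 to 13000000, with protein-coding genes drawn underneath by strand. The 3 tallest lines, at 12956025, 12980838 and 12996378, are the peaks nearest to CG13321, Psc and Su(z)2, with signals of 47845, 44865 and 48503.

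The replicates shared most of their strongest peaks. Replicates 1 and 2 shared 74.0% of the 7476 strongest, replicates 1 and 3 shared 63.6%, and replicates 2 and 3 shared 64.9%, against 1.12% by chance in each pair (permutation by circular shifts, one-sided p = 0.001, the smallest they can give). Between the full lists of 30000 peaks, the shares for these pairs were 56.2%, 42.8% and 44.3%. Correlations were taken over IDR-thresholded peaks with a summit within 100 bp in both lists of a pair (6850, 6264 and 6270 peaks). Spearman's rho was 0.828, 0.751 and 0.756, and Pearson's r of log2 signal was 0.921, 0.861 and 0.865. These are correlations across peaks, which are not independent replicates. The peaks were the 7476 strongest of the list pooled from the same replicates, so they were not chosen independently of these signals. Of the IDR-thresholded peaks, 56.2% had a summit among the 7476 strongest of all 3 replicates, and 80.9% in all 3 full lists of 30000. In none of the full replicate lists was there a summit for 13 of them.

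Nf-YC peaks lay mainly at promoters. Summits within 500 bp of a protein-coding TSS made up 53.3% of the set (3985 peaks), against 11.5% ± 0.369 (SD over 1000 random sets; permutation, one-sided p = 0.001, the smallest they can give). In the replicates' own strongest peaks the share was 53.6% ± 1.45 (SD, n = 3). Outside these promoter windows, introns held 27.0% of all summits against 38.9% of random positions, intergenic sequence 15.7% against 28.5%, and coding exons 0.535% against 14.2%. In total 4265 genes were bound, 30.6% of the 13945.

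Head-to-head promoters were bound more often than others. Of 3481 genes with an opposite-strand TSS within 500 bp upstream, 51.7% were bound, against 23.6% of the other 10464 genes (odds ratio 3.46, 95% interval 3.20 to 3.75, Fisher's exact p = 2.65e-202). One summit can score both genes of a pair, so part of this difference is set by the definition. In a test chosen after the data were seen, with each pair counted once, 53.2% of 1690 head-to-head pairs had a bound gene, against 41.1% of 5232 random pairs of other genes (odds ratio 1.63, 95% interval 1.46 to 1.82, Fisher's exact p = 3.41e-18).

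CCAAT was more frequent at strong peaks than at weak ones. Among the strongest 25% of peaks, 46.2% had CCAAT within 100 bp of the summit, against 33.7% among the weakest 25% (odds ratio 1.69, 95% interval 1.48 to 1.92, Fisher's exact p = 8.52e-15). The share was 54.1% in the strongest 10% and lay between 32.8% and 35.7% from the strongest 30% downward. In the replicates' own lists the odds ratio was 1.61 ± 0.0974 (SD, n = 3). CCAAT was also 1.22 times as dense within 50 bp of the summit as in the flanks (95% bootstrap interval 1.16 to 1.29).

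**Figure D2:**
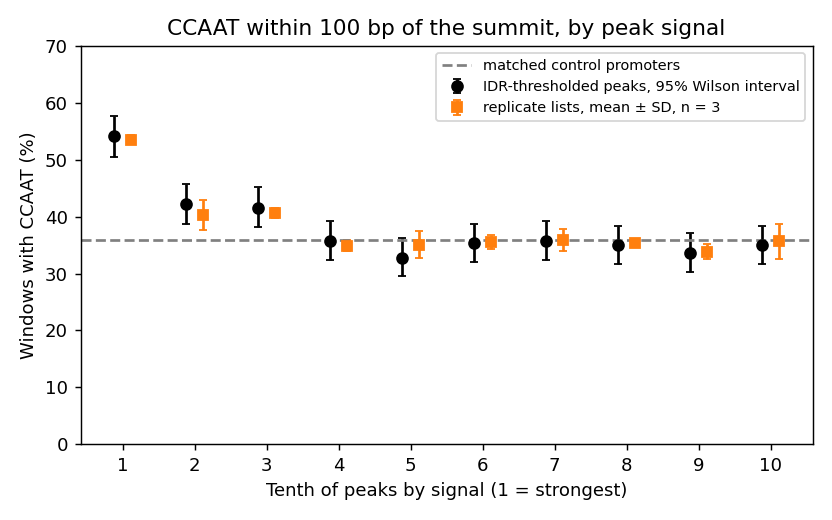
Percent of windows with CCAAT within 100 bp of the summit (vertical axis) for 10 classes of peaks by signal, strongest first (horizontal axis). Black points are all IDR-thresholded peaks with 95% Wilson intervals, orange squares are the mean ± SD of the 3 replicate lists, and the dashed line is the share in control windows matched to promoter peaks. The strongest class stands at 54.1%, and the dashed line at 35.9%.

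Over all promoter peaks, CCAAT was not called more frequent than at matched promoters of unbound genes. It was present at 37.1% of 3985 promoter peaks and 35.9% of control windows (odds ratio 1.05, 95% interval 0.962 to 1.15, Fisher's exact p = 0.274). The strongest 25% of promoter peaks had 44.6% against 33.9% in their controls (odds ratio 1.57, exact p = 1.14e-06), and the weakest 25% had 33.3% against 36.6% (odds ratio 0.864, exact p = 0.133). The overall call depended on the draw of controls, since 28 of 99 other draws gave a p under 0.05. It passed the threshold with each replicate left out (odds ratio 1.13 to 1.22), in stricter sets of 4752 to 5532 peaks.

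Of 2080 hexamers, 69 were called more frequent at promoter peaks than in the same controls, and 139 were less frequent at peaks by the same margin. At any odds ratio, 710 had an adjusted p under 0.05 (Fisher's exact test). The controls were matched on offset from the TSS and not on base composition. A broad difference in sequence is therefore not separated here from single motifs. AGAGAG, the repeat recognised by GAGA factor, was in 15.2% of promoter peaks and 8.03% of controls (odds ratio 2.05, Fisher's exact test, adjusted p = 4.20e-20). CGATAG, which shares the bases CGATA with the DNA replication-related element TATCGATA, was in 16.96% and 9.56% (odds ratio 1.93, exact adjusted p = 1.65e-19). By p, AGAGCG, ACACAC and GTGTGA followed, with odds ratios of 2.03, 1.89 and 1.91. Of the hexamers holding CCAAT, ACCAAT was more frequent at peaks (13.6% against 10.9%, exact adjusted p = 0.00186) but its odds ratio of 1.28 was under the set minimum. No other hexamer holding CCAAT had an adjusted p under 0.05. Their odds ratios were 1.17, 1.11 and 1.03 for CCAATC, GCCAAT and CCAATA. They were 0.965, 0.897, 0.848 and 0.836 for CCAATT, CCAATG, TCCAAT and CCCAAT.

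Of the 41 lists tested, the segmentation and Hox list had the largest share of bound genes. It had 29 of 30 genes bound (96.7%, against 30.4% of other genes, odds ratio 66.3, Fisher's exact test, adjusted p = 1.95e-13), and 25 of the 29 carried a peak from the strongest 25%. The odds ratio was 49.1, 32.8 and 28.3 without replicates 1, 2 and 3, 16.6 with 1 TSS per gene and 121 with a 1000 bp window, past the threshold each time. In the weaker 75% of peaks, a setting chosen after the data were seen, it was 0.788 and the call ended (exact adjusted p = 0.896). The strongest peaks of the list were at opa, at the signalling gene wg (signal 19330, 188 bp upstream), at the homeobox gene inv (17634, 113 bp upstream) and at odd (15597, 42 bp upstream). The unbound member was ftz, named after its value was seen. Cytosolic ribosomal protein genes were bound in 57 of 70 cases (81.4%, odds ratio 10.1, exact adjusted p = 3.58e-17), with peaks at RpS27, RpL32 and RpL13 that had signals from 1162 to 1666. The RpL13 peak was the same as that of Dref, in whose 5′ UTR it lay.

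The endoplasmic reticulum stress list had 16 of 20 bound (odds ratio 9.11, Fisher's exact test, adjusted p = 4.23e-05), led by Calr, Xbp1, Hsc70-3 and Herp. Xbp1, a transcription factor of the unfolded protein response, had a replicate signal of 3714 ± 1361 (SD, n = 3), 45 bp upstream of its TSS. Autophagy genes were bound in 15 of 20 cases (exact adjusted p = 0.000279), led by Atg2, Atg4b, Atg17 and Atg18a. A TSS of another gene was nearer to the Atg17 summit (148 against 231 bp). Proteasome genes were bound in 20 of 32 (exact adjusted p = 0.00129) and chaperone genes in 20 of 35 (exact adjusted p = 0.00462). Their strongest peaks were at Rpn11, Rpn6, Rpn13 and Rpn5 (in an intron of Hat1), and at Hsc70-3, Hsc70-5, Hsp83 and Hsp27. Both calls ended without replicate 1 (exact adjusted p = 0.104 and 0.504) and without replicate 2 (exact adjusted p = 0.107 and 0.230), and that of the chaperones also in the upper 50% of peaks by signal (exact adjusted p = 0.373).

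The Polycomb and trithorax list had 15 of 22 bound (odds ratio 4.88, Fisher's exact test, adjusted p = 0.00129), led by Su(z)2, Psc, ph-d and ph-p. Architectural factors had 10 of 15 bound (exact adjusted p = 0.0125), led by Chro (signal 36550), Cp190, M1BP and Dref. Glycolysis genes were bound in 9 of 13 cases (exact adjusted p = 0.0127), led by Gapdh2, Pgk, Hex-A and Eno. Apoptosis genes were bound in 9 of 12 (exact adjusted p = 0.00619), led by the death activators grim, rpr, skl and hid. The apoptosis call ended in the upper 50% of peaks by signal (odds ratio 2.32, exact adjusted p = 0.372). In the weaker 75% of peaks, a setting chosen after the data were seen, the Polycomb and trithorax, architectural, glycolysis and apoptosis calls all ended (exact adjusted p = 0.147, 0.123, 0.166 and 0.0959). Mitochondrial ribosomal protein genes were bound in 36 of 73 (odds ratio 2.22, exact adjusted p = 0.00308), led by mRpL41, mRpS10, mRpL30 and mRpS23. A TSS of another gene was nearer to the summits at mRpS10, mRpL30 and mRpS23 (128 against 129, 108 against 349 and 110 against 382 bp). The call of this list ended when head-to-head promoters were stratified by the Mantel-Haenszel method (odds ratio 1.31).

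General transcription genes were bound in 19 of 37 cases (Fisher's exact test, adjusted p = 0.0283), led by Polr2J, Taf5, Polr2B and TfIIB. A TSS of another gene was nearer to the summits at Taf5 and TfIIB (140 against 161 and 108 against 312 bp). Ras pathway genes were bound in 11 of 19 (exact adjusted p = 0.0486), led by pnt, spi, aos (in an intron of CG33158) and vn. These calls, and that of the serine protease list, ended without any 1 of the replicates. The exact adjusted p was then 0.132, 1 and 0.208 for general transcription without replicates 1, 2 and 3, 0.209, 0.105 and 0.0622 for the Ras pathway, and 0.209, 0.298 and 0.185 for the serine proteases. In the upper 50% of peaks it was 0.231, 0.117 and 0.373 for these lists.

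Of the 18 lists past the threshold, 5 were bound less often than other genes. Chemoreceptor genes were bound in 2 of 179 cases (odds ratio 0.0252, Fisher's exact test, adjusted p = 5.44e-24), at Gr63a and Gr97a. Both summits lay nearer to the TSS of another gene, and that at Gr97a, 460 bp from its TSS, was in the 5′ UTR of CG5521. Cuticle genes were bound in 2 of 120 (exact adjusted p = 1.87e-15), at Cpr67B and Cpr67Fb, and seminal protein genes in 1 of 47 (exact adjusted p = 9.17e-06), at Sfp26Ad, where the summit lay in the 5′ UTR of Gpdh1. The serine protease list had 4 of 34 genes bound (exact adjusted p = 0.0362), at Jon65Ai, SP555, SP2353 and SP1173. Its members were all matched by a pattern in the gene symbol, and what they encode was not checked. The SP genes may therefore not be serine proteases, and the call describes the list as matched. The Jon65Ai summit lay nearer to a TSS of another gene (231 against 462 bp). None of the 111 replication-dependent histone genes was bound (0 of 111, exact adjusted p = 4.52e-17), and all 111 had promoters made mostly of repeated sequence.

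**Figure D3:**
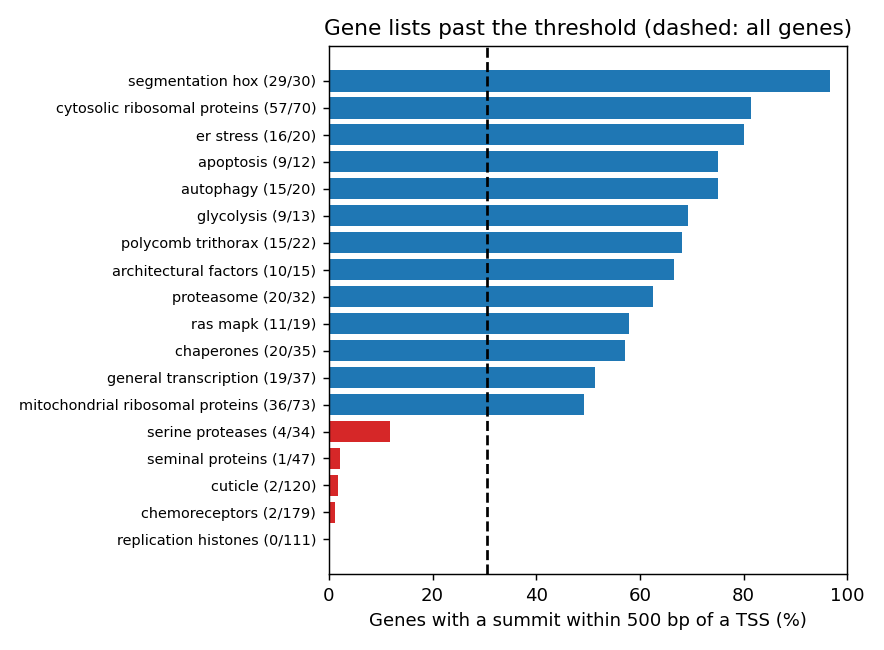
Percent of genes with a summit within 500 bp of a TSS (horizontal axis) for the 18 gene lists past the threshold, with bound and total genes beside each name. Blue bars are lists bound more often and red bars lists bound less often than other genes, and the dashed line marks the 30.6% of all genes. The segmentation and Hox list reaches 96.7% and the replication histone list stands at 0.

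The other 23 lists did not pass the threshold. Mitotic regulators were bound in 11 of 31 cases (exact adjusted p = 0.638) and DNA replication genes in 11 of 29 (exact adjusted p = 0.517). Dorsoventral patterning genes were bound in 9 of 16 (odds ratio 2.92, Fisher's exact test, adjusted p = 0.0933), and passed without replicate 1, 2 or 3 (exact adjusted p = 0.00260, 0.00994 and 0.0165). Notch pathway genes, with 10 of 18 bound (exact adjusted p = 0.0711), passed without replicates 2 and 3 (exact adjusted p = 0.0217 and 0.00352). Hippo pathway genes, with 8 of 13 (exact adjusted p = 0.0629), passed without replicate 3 (exact adjusted p = 0.0470), and mitotic regulators passed without replicate 2 (exact adjusted p = 0.0352). In the upper 50% of peaks, the dorsoventral, Notch, Hippo, and blood cell and fat body lists passed (exact adjusted p = 0.00310, 0.00226, 0.0467 and 0.0491). Within 250 bp of a TSS, the Mediator, Notch, translation factor and Wnt lists passed (exact adjusted p = 0.0367, 0.0244, 0.0210 and 0.0305). Within 1000 bp the dorsoventral, Hippo and Notch lists did (exact adjusted p = 0.0177, 0.0325 and 0.0448), and with 1 TSS per gene the Hippo and Notch lists (exact adjusted p = 0.0316 and 0.0383). With head-to-head promoters stratified, the dorsoventral, Notch and Wnt lists passed (odds ratio 4.01, 2.78 and 2.75). Muscle genes (7 of 20), neuronal genes (8 of 22), glial genes (4 of 8) and blood cell and fat body genes (7 of 17) did not differ past the threshold.

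Among the NF-Y subunit genes, Nf-YA had a peak on 3L (9442188 to 9442425), 31 bp upstream of its TSS, with a replicate signal of 137 ± 26.6 (SD, n = 3). A TSS of another gene was equally near (31 bp), so the peak cannot be assigned to Nf-YA alone. It ranked 4265 in the set. Nf-YB and Nf-YC had none within 500 bp, and the nearest summits were 20827 and 17361 bp from their TSSs. Of the 12 candidate genes, 7 were bound (exact adjusted p = 0.0942), and the list passed within 250 bp of a TSS (odds ratio 3.95, exact adjusted p = 0.0345). They were Hsc70-3, Hsp83, sens, Cdk1, E2f1, Xbp1 and p53. The peak at sens, a zinc-finger gene of sensory organ development, had a replicate signal of 497 ± 164 (SD, n = 3), that at Cdk1 164 ± 59.5, and that at p53 102 ± 12.01. The Cdk1 peak was also that of mRpS7, whose TSS was nearer (156 against 244 bp). At E2f1 the SD exceeded the mean (105 ± 116, n = 3). The genes bsk, CycB, rl, sev and stg had no IDR-thresholded summit within 500 bp of a TSS. At stg, each full replicate list had 2 summits there. The IDR-thresholded summit nearest to rl was 4621474 bp away, so the lack of a peak is not particular to that gene.

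Genes on the X chromosome were bound in 33.8% of cases and those on arms 2L, 2R, 3L and 3R in 29.98% (odds ratio 1.19, 95% interval 1.08 to 1.32, Fisher's exact p = 0.00037). The difference did not hold without replicate 1, 2 or 3 (odds ratio 0.925, 1.02 and 0.988) or in the upper 50% of peaks by signal (0.892). It was kept with windows of 250 and 1000 bp (1.12 and 1.22), as peaks per Mb (1.10) and with shoulder summits removed (1.19 to 1.20). In the replicates' own strongest peaks, the X share was 32.0%, 31.8% and 31.01%, against 29.0%, 31.1% and 32.0% on these arms. On chromosome 4, 24 of 80 genes were bound.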

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

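The alternatives removing shoulder summits, redrawing controls, keeping unique promoters, keeping the weaker 75% of peaks or counting head-to-head pairs once were chosen after seeing the data. The 7476 strongest peaks of the pooled list were the same peaks as the IDR-thresholded set, so using them tested nothing. Depth is unknown and limits what can be said of weak peaks. No paired analysis was possible because the replicates form 1 group. Promoter share, centring, CCAAT by strength, hexamer number and head-to-head promoters kept their direction and side of the threshold, or their count within 1.5 times, in every alternative run, and so did replicate overlap against its own chance level. Hexamer identity moved more, with 40 to 57 of the 69 shared across the alternatives that changed the windows or peaks.

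The peak number was 3738 in the upper 50% by signal and 4752 to 5532 with a replicate left out, which follows from keeping fewer peaks. The mean rho between replicates was 0.832 with summits within 50 bp, and 0.751 to 0.828 with a replicate left out. The CCAAT odds ratio of 1.05 passed the threshold in the upper 50% (1.19), with a replicate left out (1.13 to 1.22), against shuffled windows (1.19), for RRCCAAT (1.21) and with shoulders within 300 bp (1.13) or 1000 bp removed (1.11), but not with those within 500 bp removed (1.10, exact p = 0.0575), in windows of 50 or 200 bp (1.05 and 1.02, exact p = 0.348 and 0.650) or against flanks 400 bp away (1.09, exact p = 0.0621). Over 99 other draws of controls it ran from 0.990 to 1.16. The X odds ratio was 0.892 in the upper 50% and 0.925 to 1.02 with a replicate left out. The cause was not tested for these.

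The list count was 11 of 18 in the weaker 75% of peaks, where the segmentation and Hox odds ratio was 0.788, dorsoventral 0.450, early zygotic 1.05, neuronal 0.315, glial 0.185 and blood cell and fat body 0.420. Fewer strong peaks are kept there by construction. None of these, nor of the other list odds ratios that turned direction, was past the threshold in that setting. In the upper 50% they were DNA replication 0.966, oxidative phosphorylation 0.927, histone variants 0.927 and circadian 0.244. With a replicate left out they ran from 0.993 to 2.13 for DNA replication, 0.997 to 1.89 for general transcription, 0.284 to 1.16 for early zygotic, 0.892 to 1.74 for circadian and 0.347 to 0.803 for E(spl). Muscle was 0.497 at 250 bp and 0.848 with 1 TSS per gene, and with head-to-head strata mitotic regulators were 0.880 and tRNA synthetases 0.719. The cause was not tested.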

Other observations

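The tests of motifs by signal, GAGAG, peak strength per gene list, non-coding genes, gene density of strong peaks and shoulder summits below were chosen after the peak set was seen.

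Of 6 motifs tested beside CCAAT, 4 differed between strong and weak peaks. GAGAG was within 100 bp of the summit in 40.3% of the strongest 25% of peaks and 29.2% of the weakest 25% (odds ratio 1.64, Fisher's exact test, adjusted p = 3.78e-12 over 7 motifs). The motif GGTCACAC, a core promoter element, went the other way, at 1.28% against 4.601% (odds ratio 0.270, exact adjusted p = 3.07e-09), as did the DNA replication-related element TATCGATA, at 2.46% against 4.12% (odds ratio 0.587, exact adjusted p = 0.00803), and CAGCTG, at 9.31% against 12.2% (odds ratio 0.739, exact adjusted p = 0.00803). CAGGTAG (1.66% against 0.963%, exact adjusted p = 0.0973) and TATAAA (25.5% against 25.9%, exact adjusted p = 0.793) did not differ past the threshold. At promoter peaks nearest to segmentation and Hox genes, 29 of 35 had GAGAG, against 28.1% of other promoter peaks (odds ratio 12.4, Fisher's exact p = 3.10e-11). The other promoter peaks were of all strengths, so part of this difference may be the rise of GAGAG with signal. Of the 29 bound genes of that list, 25 carried a peak of the strongest 25%. Among bound genes, those of the segmentation and Hox list, the dorsoventral list (9 of 9) and the neuronal list (7 of 8) carried a peak of the strongest 25% more often than other bound genes (Fisher's exact test, adjusted p = 5.08e-09, 0.000243 and 0.0122).

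The 100000 bp window with the largest number of strong summits was on 2R from 12900001 to 13000000. It held 17 such summits, against a mean of 1.33, and contains Psc and part of Su(z)2. Another 3 held 11, on X from 2100001 with ph-d and ph-p, on 3R from 11300001 with pros, and on 3R from 23200001 with pnt, orb and cnc. The next, with 10, was on 3R from 16900001 with Abd-B. Of non-coding genes, 28 of 290 tRNA genes had a summit within 500 bp, 9.66% against 4.66% of random positions (odds ratio 2.19, Fisher's exact test, adjusted p = 0.00129), as did 6 of 32 snRNA genes (odds ratio 5.24, exact adjusted p = 0.00424) and 344 of 3261 other non-coding RNA genes (10.5% against 4.99%, odds ratio 2.25, exact adjusted p = 1.06e-34). For snoRNA genes the difference did not pass (7.43% against 5.24%, exact adjusted p = 0.125). The random positions were not matched on distance to protein-coding TSSs, near which 53.3% of summits lay. Peaks at neighbouring protein-coding promoters are therefore not separated from peaks of the non-coding genes.

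The first pattern is the rise of CCAAT with peak signal. Shoulder summits near a stronger one do not account for it, since the odds ratio was 1.78 with them removed within 500 bp (95% interval 1.54 to 2.04). The strongest 25% exceeded their own dinucleotide-shuffled windows 1.72 times as much as the weakest 25%, as a ratio of odds ratios (95% interval 1.42 to 2.07). Shuffled windows held CCAAT in 33.4% of the strongest 25% and 33.8% of the weakest 25%. These values argue against dinucleotide composition as the cause of the rise. Nor did GAGAG account for it, since the odds ratio was 1.64 among peaks without GAGAG (95% interval 1.39 to 1.93). Other GA-rich sequence was not removed and was not tested. One hypothesis is that the strongest peaks include direct binding of the NF-Y trimer and that many weaker ones may not, but no biological explanation was tested, since there is 1 group and no pull-down from another line was analysed here.

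The second pattern is the strong binding at segmentation and Hox genes. A larger number of annotated start sites is not the whole cause, since the odds ratio stratified by their number was 79.5 (95% interval 9.25 to 683). With 1 TSS per gene it fell from 66.3 to 16.6 and stayed past the threshold (exact adjusted p = 3.09e-10). Pull-down at open promoters without NF-Y sequence stays open. CCAAT was at 28.6% of the 35 promoter peaks of these genes and 35.9% of control windows (odds ratio 0.714, 95% interval 0.357 to 1.51). The controls were those of all 3985 promoter peaks. With so few peaks the interval spans CCAAT both rarer and more frequent than in controls, so the test cannot decide. No biological explanation was tested.

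The third pattern is the lack of peaks at the replication-dependent histone genes, which lie on 2L between 21416953 and 21541681. Reads from repeated copies that were not placed could account for it. Of 213 other genes with mostly repeated promoters, 3.76% had a summit in the full pooled list, against 47.3% of genes with unique promoters (odds ratio 0.0434, 95% interval 0.0232 to 0.0915, Fisher's exact p = 1.15e-45). Genes in repeats also differ from others in ways not tested here, and binding at the histone genes is therefore neither shown nor excluded.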
